A study of Homo sapiens and Homo sapiens
Mus musculus and Mus musculus with 31 samples.

How the data were processed

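The deposited files hold raw UMI counts per gene and barcode or spot; the authors had made these counts with STAR 2.5.1, Cell Ranger and Space Ranger against the builds hg38 and mm10, per the submitters' processing notes, which do not say which tool made which file. The inDrop files list protein-coding genes and keep 2000 barcodes per library, the mouse files keep 10000 barcodes per library with the counts of antibody tags, and the section files keep the spots over tissue. Gene positions for human genes came from GENCODE 29 on GRCh38, the assembly also called hg38; mouse gene positions were not looked up. The 1 section titled pancreatic carries a characteristic that names another organ, and it was grouped by its title. Choices of groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, apart from those named as added.

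Barcodes were kept as cells at 500 or more UMIs (inDrop) or 1000 or more (mouse and xenograft) and at most 30% mitochondrial UMIs. This left 23735 of 70000 inDrop barcodes in 35 libraries, 32369 of 50000 mouse barcodes in 5 libraries and 2604 of 3754 xenograft barcodes. Libraries held 350445 to 4627434 UMIs (inDrop) and 40125955 to 151561152 UMIs (mouse), with medians of 759.5 to 3037 and of 4382 to 15330 UMIs per cell. XIST and Y-linked genes were removed from every table. Simulated pairs of cells from the same library gave a doublet score, and the 5% (inDrop) or 8% (10x) of cells with the highest scores were left out of sums by class, 1189 inDrop, 2590 mouse and 208 xenograft cells. Cells of each tumour or mouse sample were clustered with the Leiden algorithm (resolution 1, seed 0) on 20 nearest neighbours in 20 principal components of 2000 variable genes, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2. Figures were drawn with matplotlib 3.10.9.

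Each cluster took the class whose detected markers, at least 3, had the highest mean log2 fold over the other classes, scaled to that class's highest cluster. The human lists were epithelial (such as EPCAM and KRT8), GIST (KIT, ANO1), hepatocyte (ALB, TTR), renal (PAX8, CDH16), T or NK (CD3D, NKG7), B (MS4A1), plasma (JCHAIN), macrophage (CD68, C1QA), mast (TPSAB1), fibroblast (DCN, LUM), endothelial (PECAM1, VWF), mural (RGS5) and erythroid (HBB). A melanoma list (MLANA) was kept out of the naming of clusters. The mouse lists added monocyte (Ly6c2), neutrophil (Retnlg), dendritic (Flt3), separate T (Cd3d) and NK (Ncr1), mesothelial (Upk3b) and acinar (Prss2) markers. Clusters with fewer detected markers, or whose leading genes were markers of another class or belonged to short lists of neutrophil, plasmacytoid and gastric genes written after the clusters were seen, were left unnamed. The gastric list did not apply to clusters that took the epithelial class. Of 186 inDrop clusters 15 had no name; in mouse these were 2 of 18, 2 of 19 and 2 of 24. A mouse cell belonged to a pool when its top tag had at least 20 counts and at least 3 times those of the next tag. Xenograft cells were called human or mouse at 90% of UMIs from that species.

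The 13 state lists, written from general knowledge, were cycle, stress, interferon, antigen presentation, hypoxia, oxidative phosphorylation, metallothionein, mesenchymal, partial EMT (epithelial to mesenchymal transition), squamous, basal, glandular and ciliated. Lineage lists were breast, ovary, endometrium, colon, prostate and pancreas. Several lists share genes with a cell type: antigen presentation and mesenchymal genes are also expressed by macrophages and fibroblasts, and COL1A1, COL1A2, COL3A1 and MMP2 stand in both the mesenchymal and the fibroblast list. In mouse, Fn1 stands in both the mesenchymal and the monocyte list. Krt19 stands in both the epithelial and the mesothelial list, and S100a8 and S100a9 in both the squamous and the neutrophil list. Such genes count in both lists.

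For gene tests, UMIs were summed over the epithelial-like cells of each tumour (at least 50 cells) or tagged pool. Sums held 504466 to 4030666 UMIs in BRCA, 823577 to 2286183 in OVCA and 644322 to 1151867 in UCEC. Knockout pools held 507071 to 1065322 UMIs and wild-type pools 1922475 to 6325544, liver pools 5583148 and 10175611, peritoneum pools 16290058 and 12032430, and the pools of the pancreas and peritoneum library 16229025 to 24669058. Genes passed filterByExpr of edgeR 4.0.16 (R 4.3.3), were scaled by TMM and tested with the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all genes at 0.05; DESeq2 1.42.0 was the alternative. Means and SDs of CPM in these tests are on TMM-scaled library sizes of the genes tested; bounds, pooled ratios, plots and values of single pools or classes are on unscaled totals. The SE of a log2 fold change was derived from the test, as its absolute value over the square root of the F statistic. The 9 BRCA, OVCA and UCEC tumours shared 1 fit, so OVCA against BRCA and UCEC against BRCA share their BRCA tumours. The 2 tests of mouse sites have 2 pools per site, and each condition except pancreas against peritoneum has its own library.

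Named genes were, in each direction, the 10 with the largest log2 fold change among those past the threshold whose groups did not overlap, without mitochondrial, ribosomal protein, immunoglobulin, haemoglobin and unnamed clone genes, plus the measured members of the lineage lists of the cancer types compared. For a list past its test, up to 4 members with the largest mean were named. A few genes that the rule takes are not reported here. Against a group with 0 UMIs any fold was bounded with a floor of 3 UMIs over the group; with 1 to 3 UMIs any ratio of pooled CPM is given with its 95% exact binomial interval. Floors, ratios and Clopper-Pearson intervals cover counting error only.

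Co-expression was the mean pairwise Pearson correlation of a list's genes (in at least 2% of cells, at least 3 genes) over the tumour-lineage cells of a tumour (at least 100), on the log of UMIs per 10000 plus 1, minus the mean of 200 random lists matched on size and expression. Levels were compared as log2 ratios of UMI shares with 0.5 UMIs added, and ratios of cells to sections had the median over genes subtracted. Spots needed 500 UMIs; correlations were partial Spearman correlations given the ranks of total UMIs and tumour lineage score, without genes in both lists. Differences over tumours or sections were tested with two-sided sign-flip permutation tests that enumerate every sign pattern, adjusted over the 12 or 13 lists or the 91 pairs.

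The 59 alternatives fixed in advance and those added later changed the normalisation, the test, filters, the cells or sections used and each replicate in turn. Gene tests were tested on simulated data with the depth and spread of these sums: of genes changed 4-fold, 5.15%, 7.45% and 3.06% were called in the human comparisons, and of those changed 64-fold 97.9% to 99% were; of genes changed 2-fold, 81.6%, 64.6% and 57.6% were called in the mouse comparisons of genotype, liver and pancreas. The list scores were tested the same way, with 20 of 20 and 19 of 19 driven lists above the highest of the others. Replicates were checked for copies: over 25 pairs within groups the chi-square per degree of freedom was 1.53 to 73.3, and 0 pairs were identical. Images and the spots' pixel positions were not analysed here.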

Results

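The series measured gene expression, as unique molecular identifiers (UMIs, tags that mark single captured RNA molecules), in 31 samples. Dissociated cells of 15 human tumours were profiled by inDrop, a droplet method for single cells: 3 breast carcinomas (BRCA), 3 ovarian carcinomas (OVCA), 3 endometrial carcinomas (UCEC), 2 gastrointestinal stromal tumours (GIST) and 1 each of colon (COAD), kidney (KIRC), liver (LIHC) and prostate (PRAD) carcinoma. Visium, which counts RNA over barcoded spots of a tissue section, was run on 10 sections: 3 BRCA, 2 GIST, 2 OVCA and 1 each of LIHC, UCEC and pancreatic adenocarcinoma (PDAC). For 8 tumours the titles named both assays. A human melanoma grown in mice added 2 Visium sections and 1 single-cell sample. Tumours of the mouse pancreatic cancer line FC1242 added 3 samples in 5 libraries, whose cells carried antibody tags that mark pools of cells. The series title asks which tumour cell states recur across cancer types and which cells of the microenvironment they meet.

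Total UMIs per inDrop tumour were 4627434, 1836480 and 1762144 for BRCA replicates 1 to 3, 4116423, 3968971 and 2220420 for OVCA, and 3350498, 2554136 and 1902342 for UCEC. The GIST replicates held 4897748 and 3162867 UMIs, COAD 2045041, KIRC 4013893, LIHC 4475652 and PRAD 3603190. Sections held 15706356 (BRCA0), 2166399 (BRCA1), 28101169 (BRCA2), 6434290 (GIST1), 11672062 (GIST2), 3950402 (LIHC1), 17325415 (OVCA1), 2938378 (OVCA3), 9057749 (PDAC1) and 6631104 (UCEC3) UMIs. Median UMIs per spot ran from 280 in BRCA1 to 12581.5 in BRCA2. Mouse libraries held 42038795 (Rag knockout), 41933189 (wild type), 151561152 (pancreas and peritoneum), 67126310 (peritoneum) and 40125955 (liver) UMIs. The xenograft cells held 45256216 UMIs. The first xenograft section held 5102344 human and 10577470 mouse UMIs, and the second 15616273 and 2790685.

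The 23735 inDrop cells kept fell into tumour-lineage and microenvironment classes named by marker genes. Of these cells, 8168 were epithelial-like, in 12 tumours, 90 of them in 1 GIST in a cluster led by gastric genes, and 1371 were GIST-like, 595 hepatocyte-like and 316 renal-like. T or NK-like cells numbered 5759 and macrophage-like cells 4124. Smaller classes were endothelial-like (658), fibroblast-like (472), plasma-like (357), mural-like (266), B-like (263) and mast-like (91) cells. No cluster was named erythroid, and 1295 cells had no name. Melanoma was not among the classes that an inDrop cluster could take.

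Epithelial-like cells of OVCA and BRCA were compared to ask which genes part carcinomas of different organs. Transcription factors of the Müllerian tract were among the genes that rose in OVCA. PAX8, which patterns Müllerian and renal epithelium, stood at 214 ± 56.0 counts per 1000000 UMIs (CPM, on TMM-scaled library sizes wherever a mean ± SD of CPM is given; n = 3 tumours per group throughout) in OVCA and 0.345 ± 0.597 in BRCA, and rose by a log2 fold change of 8.28 ± 0.77 (SE; edgeR adjusted p = 0.00220). Its pooled ratio was 389 (95% exact interval 133 to 1891; 974 against 3 UMIs), and at least 114 without BRCA1, which held the 3 UMIs. It sits on chromosome 2 at 113215997 to 113278950 (minus strand; GRCh38, GENCODE 29). SOX17, an endoderm and reproductive tract factor (chromosome 8, 54457935 to 54460888, plus strand), stood at 309 ± 170 CPM in OVCA and 0 UMIs in BRCA, at least 516-fold higher (151-fold without BRCA1 and 792-fold without OVCA1; adjusted p = 0.0209). EMX2, a homeobox factor of the urogenital system (chromosome 10, 117542444 to 117549546, plus strand), stood at 195 ± 45.7 CPM against 0 UMIs, at least 398-fold higher (117-fold without BRCA1; adjusted p = 0.00220). MECOM, a zinc finger factor (chromosome 3, 169083499 to 169663618, minus strand), had 524 UMIs in OVCA and 1 in BRCA, a pooled ratio of 628 (95% exact interval 112 to 24866; adjusted p = 0.00220). Without BRCA1, which held that UMI, MECOM was at least 61.5-fold higher.

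The breast factor FOXA1 and several genes of secreted proteins fell in OVCA, while the glandular list of secreted proteins had 0 of 12 genes past the test over all genes. FOXA1, a pioneer factor of luminal breast cells (chromosome 14, 37589984 to 37596059, minus strand), fell by 5.31 ± 0.91 on the log2 scale, from 430 ± 66.4 to 11.02 ± 9.35 CPM (adjusted p = 0.0416). PIP, an apocrine secreted protein (chromosome 7, 143132077 to 143139746, plus strand), stood at 0.803 ± 1.39 CPM in OVCA and 3333 ± 2824 in BRCA (log2 fold change -11.79 ± 1.60, adjusted p = 0.0209). AZGP1, a secreted glycoprotein (chromosome 7, 99966720 to 99976157, minus strand), stood at 5.62 ± 9.74 against 2343 ± 49.8 CPM (log2 fold change -8.63 ± 1.53, adjusted p = 0.0433). Its OVCA value came from OVCA2 (17.0 CPM on unscaled totals), with 0 in OVCA1 and OVCA3. MGP, a matrix protein (chromosome 12, 14881181 to 14885926, minus strand), stood at 20.3 ± 26.5 against 10955 ± 10587 CPM (adjusted p = 0.0433). TFF1, an oestrogen-responsive trefoil peptide (chromosome 21, 42362282 to 42366594, minus strand), had 2 UMIs in OVCA and 26479 in BRCA, a pooled ratio of 11041 (interval 3056 to 91171; adjusted p = 0.0387). The TFF1 ratio was 1432 without BRCA1, 5735 without OVCA1 and 18258 without OVCA3. The other named genes that rose were STXBP6, FOXQ1, ST6GALNAC1, DACT2 and ZNF280B, with 626, 327, 226, 186 and 130 UMIs in OVCA and 0 in BRCA, and TMPRSS4 (417 against 3 UMIs). The other named genes that fell were TFAP2B and LMX1B (0 UMIs in OVCA against 754 and 150), CLSTN2 (2 against 404), EEF1A2 (2 against 273), APOD (-7.85 ± 1.39) and CEACAM6 (-7.30 ± 1.36).

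By list, 3 of 7 measured ovary genes rose (5 when adjusted over the list alone), 3 of 7 endometrium genes rose (4 over the list alone) and 2 of 8 breast genes fell (6 over the list alone). Breast members short of the threshold over all genes included GATA3, a luminal factor (-6.33 ± 1.28, adjusted p = 0.0566), and TRPS1 (-3.30 ± 0.64, adjusted p = 0.0522), while the oestrogen receptor gene ESR1 was at -1.62 ± 0.74 (adjusted p = 0.347). GATA3 stood at 66.9 CPM on unscaled totals in OVCA1 and at 4.25 and 2.43 in OVCA2 and OVCA3. SCGB2A2 stood at -9.85 ± 1.91, MUCL1 at -3.03 ± 2.58, and ANKRD30A had 0 UMIs in OVCA (adjusted p = 0.0522, 0.659 and 0.0795). Of the ovary list, MSLN had 581 against 2 UMIs (adjusted p = 0.0672), and MUC16 (3.85 ± 1.37), KLK7 (5.09 ± 2.26) and FOLR1 (1.87 ± 1.52) also missed the threshold. The pancreas list lost 2 of 3 genes, TFF1 and CEACAM6 (3 over the list alone); 0 of 1 colon and 0 of 3 prostate genes passed (2 prostate genes were lower over the list alone). Genes of motile cilia were all 12 higher in OVCA, 0 past the threshold over all genes and 9 when adjusted over the list alone, such as CFAP126 (4.04 ± 0.87, adjusted p = 0.0640). In the mesenchymal list 1 of 12 genes rose, IGFBP7, a secreted insulin-like growth factor binding protein (6.47 ± 1.20, adjusted p = 0.0470), and over the list alone 2 were higher and 2 lower. No member passed over all genes in the other 11 state lists; over the list alone, 2 metallothionein, 2 squamous, 2 basal and 2 glandular genes were higher, 2 stress genes were lower, and 0 cycle, interferon, antigen presentation, hypoxia, oxidative phosphorylation and partial EMT genes passed.

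Markers of other cell types were measured in the same sums. The macrophage marker MS4A7 fell by 6.23 ± 1.05 (adjusted p = 0.0410), 1 of 9 measured macrophage markers, and the renal list held PAX8, 1 of 4. Of the T or NK (2 measured), B (1), plasma (1), fibroblast (5), endothelial (2), mural (4), erythroid (3), GIST (2), hepatocyte (1), melanoma (1) and epithelial (10) markers, 0 passed over all genes. Adjusted over the list alone, 1 plasma, 1 GIST, 1 melanoma and 1 fibroblast marker were higher and 1 renal and 1 fibroblast marker lower. No mast marker was measured in these sums.

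**Figure D1:**
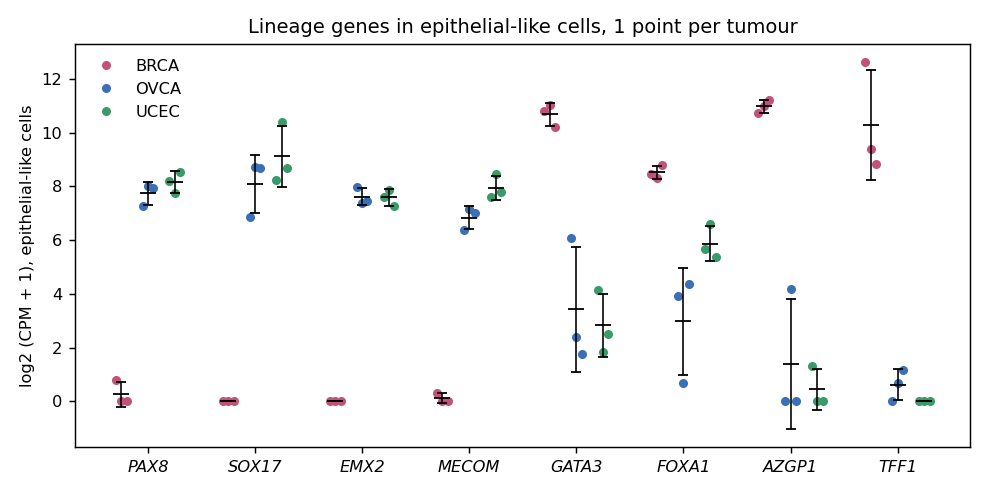
Log2 of CPM plus 1 (on unscaled totals) in the epithelial-like cells of each BRCA, OVCA and UCEC tumour for lineage genes, with points for tumours and black bars for the mean ± SD of the log values (n = 3). SOX17 and EMX2 had 0 UMIs in the 3 BRCA tumours, and SOX17 lay between 115 and 417 CPM and EMX2 between 168 and 251 CPM in the OVCA tumours.

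In all, 31 genes rose and 33 fell of 11160 tested (edgeR quasi-likelihood, two-sided), and all 64 had groups that did not overlap, against 15.3% of all genes and 10% by chance. The count was 8 (3 rose and 5 fell), 18 (7 and 11) and 147 (84 and 63) without BRCA replicates 1, 2 and 3. It was 203 (165 and 38), 28 (20 and 8) and 6 (6 and 0) without OVCA replicates 1, 2 and 3, so no fallen call was left without the last. DESeq2 gave 736 (466 and 270), and all cells of each tumour gave 11 (4 and 7).

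UCEC against BRCA asked the same question for a second gynaecological cancer. UCEC cells held MECOM at 238 ± 76.0 CPM (673 UMIs against 1, ratio 1560, interval 279 to 61725, and at least 153-fold without BRCA1; adjusted p = 0.00130) and PAX8 at 274 ± 69.6 CPM (log2 fold change 8.63 ± 0.78, pooled ratio 529, interval 180.1 to 2570, and at least 155 without BRCA1; adjusted p = 0.00216). SOX17 at 647 ± 545 CPM was at least 1577-fold higher (463-fold without BRCA1 and 680-fold without UCEC2) and EMX2 at 182 ± 40.1 CPM at least 386-fold higher (113-fold without BRCA1), each against 0 UMIs in BRCA. STXBP6, CD200 (a membrane glycoprotein that restrains myeloid cells), ST6GALNAC1, DACT2 and GALNT12 had 569, 228, 137, 140 and 61 UMIs in UCEC and 0 in BRCA. UGT2B7, a glucuronidation enzyme with close relatives that share reads, had 281 against 0.

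GATA3 (chromosome 10, 8045378 to 8075203, plus strand) fell by 8.11 ± 1.42, from 2009 ± 743 to 7.50 ± 7.28 CPM (adjusted p = 0.0407). IRX2 fell by 6.57 ± 1.09, to 4.53 ± 1.82 CPM from 454 ± 191 (adjusted p = 0.0391), and MGP fell by 12.16 ± 1.85 (7 UMIs against 71723; adjusted p = 0.0284). TFF1 had 0 UMIs in UCEC and was at least 3807-fold lower (494-fold without BRCA1 and 2024-fold without UCEC2). LRP2, an endocytic receptor, had 0 UMIs in UCEC and 895 in BRCA. AZGP1 (1 UMI against 10453), PIP (2 against 9813), PDLIM3 (1 against 1027), CLSTN2 (2 against 404) and EEF1A2 (1 against 273) fell too.

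The endometrium list had 3 of 7 genes risen (5 when adjusted over the list alone), the ovary list 3 of 7 (4 over the list alone) and the breast list 2 of 8 fallen (7 over the list alone). MSX1, a homeobox factor of endometrium, stood at 729 ± 436 against 4.24 ± 2.49 CPM (7.24 ± 1.61, adjusted p = 0.0681). HOXA10 (4.28 ± 1.75, adjusted p = 0.255), the progesterone receptor gene PGR (0.85 ± 1.67, adjusted p = 0.859) and SCGB2A1 (-2.58 ± 1.81, adjusted p = 0.538) missed the threshold, as did FOXA1 (-2.89 ± 0.81), TRPS1 (-3.10 ± 0.63), ESR1 (-0.53 ± 0.73), SCGB2A2 (-8.96 ± 1.85), MUCL1 (1 UMI in UCEC against 2752) and ANKRD30A (0 UMIs in UCEC, adjusted p = 0.0786). Stress genes, immediate early factors and heat shock genes, passed in 0 of 15 over all genes and 8 were lower over the list alone, such as ATF3 (-2.09 ± 0.44, adjusted p = 0.0610) and KLF6 (-2.21 ± 0.48). All 12 ciliated genes were positive, 5 past the test over the list alone. The pancreas list lost TFF1, 1 of 3 (2 over the list alone), and 0 of 1 colon and 0 of 3 prostate genes passed. Over the list alone, the mesenchymal list had 3 higher and 4 lower of 12, partial EMT 2 higher and 1 lower of 13, glandular 2 higher and 1 lower of 12, metallothionein 1 higher of 7, squamous 1 higher of 5 and basal 1 higher and 1 lower of 5; none passed over all genes. Cycle, interferon, antigen presentation, hypoxia and oxidative phosphorylation genes passed in 0 cases under either adjustment.

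Among markers of other cells, PAX8 and LRP2 of the renal list passed over all genes. Over the list alone, 4 macrophage markers were higher and 1 lower of 9, 1 fibroblast marker was higher and 4 were lower of 5, and 3 of 10 epithelial markers were lower, with 1 T or NK, 1 plasma, 1 melanoma and 2 renal markers higher. In all, 26 genes rose and 29 fell of 11160, all 55 with groups that did not overlap (22.1% of all genes; 10% by chance). The count was 7 (3 rose and 4 fell) and 138 (77 and 61) without BRCA replicates 1 and 3, and 6 (5 and 1), 14 (12 and 2) and 4 (4 and 0) without UCEC replicates 1, 2 and 3. It was 850 with DESeq2, 100 with all cells and 83 with cells of at least 1000 UMIs.

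OVCA and UCEC cells were then set against each other. PAX8 (-0.36 ± 0.50), EMX2 (0.10 ± 0.43) and SOX17 (-1.07 ± 0.73) had log2 fold changes near their errors, and MSLN (1.39 ± 1.15), KLK7 (3.72 ± 2.01), MUC16 (0.89 ± 1.22), FOLR1 (-1.73 ± 1.44), HOXA10 (-1.20 ± 1.42), PGR (-0.71 ± 1.67), MSX1 (-0.49 ± 1.20) and SCGB2A1 (2.58 ± 1.81) also missed the threshold (adjusted p = 0.999 for each). All 12 ciliated and all 7 metallothionein genes were higher in OVCA, and 15 of 16 cycle genes were lower, none past the test. Over the list alone, 3 mesenchymal genes, 1 fibroblast marker and 1 endothelial marker were higher, and no other state, lineage or cell type list had a gene past the test. edgeR called 0 of 11160 genes, with 334 at an unadjusted p under 0.05, and DESeq2 called 3; groups did not overlap for 9.34% of genes, against 10% by chance.

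Within each tumour, the genes of the fixed state lists were asked whether they vary together from cell to cell. Stress genes did so in all 15 tumours: their mean pairwise correlation over tumour-lineage cells exceeded that of matched random lists by 0.209 ± 0.0564 (SD, n = 15; sign-flip permutation, two-sided, p = 6.1e-05, the smallest possible, adjusted p = 1.8e-04). FOSB (0.325 ± 0.0845), JUN (0.315 ± 0.0791), FOS (0.312 ± 0.0751) and EGR1, immediate early transcription factors, led the list. Metallothioneins, which bind metal ions, exceeded random lists by 0.251 ± 0.165 (n = 13, all positive; adjusted p = 5.9e-04), with MT1H and MT1G highest. Genes of motile cilia exceeded random lists by 0.227 ± 0.240 in 9 tumours, 8 of them positive (exact permutation, adjusted p = 0.0195). The excess was 0.415 to 0.556 in OVCA2, OVCA3, UCEC2 and UCEC3, 0.133 in UCEC1 and -0.0261 to 0.0206 in BRCA1, BRCA2, OVCA1 and COAD1. With cells thinned to 500 UMIs or genes in at least 5% of cells, the ciliated list, scored in 6 tumours, missed the threshold (exact permutation, adjusted p = 0.0682 and 0.0625). Its mean excess was 0.220 ± 0.150 and 0.286 ± 0.226 in these settings. In the list, C20orf85 reached 0.584 ± 0.0437 in the 4 tumours where it was measured. Antigen presentation genes were positive in 15 of 15 tumours (0.110 ± 0.0503), with the class II genes CD74 (0.222 ± 0.0845), HLA-DRA and HLA-DRB1 highest. These genes were far lower in tumour-lineage cells than in other cells (mean log2 ratio -3.39 for CD74 and -4.44 for HLA-DRA). RNA from other cells was not tested as a source of their co-expression.

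Cycle genes exceeded random lists by 0.115 ± 0.0939 (14 of 15 tumours; adjusted p = 6.1e-04), led by TOP2A, UBE2C, TPX2 and CDK1. Basal keratin genes stood at 0.103 ± 0.148 (8 of 9). With thinned cells they were positive in 4 of 6 (exact permutation, adjusted p = 0.219). The basal excess was 0.450 in PRAD1, 0.211 in BRCA3 and 0.112 in UCEC3, and -0.0381 to 0.0587 in the others. Glandular secretory genes stood at 0.0800 ± 0.0653 (12 of 13) and mesenchymal genes at 0.0644 ± 0.0848 (13 of 15). RNA from other cells was not tested as a source for the mesenchymal list either. Oxidative phosphorylation genes stood at 0.0611 ± 0.0264 and interferon genes at 0.0611 ± 0.0655, each in 15 of 15. The interferon excess was 0.227 in BRCA1 and 0.188 in OVCA1, and 0.00146 (PRAD1) to 0.0889 (UCEC1) in the others. Partial EMT genes stood at 0.0471 ± 0.0550 (14 of 15) and hypoxia genes at 0.0390 ± 0.0522 (14 of 15, permutation adjusted p = 0.00198). All 12 lists tested passed. With cells thinned to 500 UMIs, stress genes exceeded random lists by 0.133 ± 0.0390, oxidative phosphorylation genes by 0.0202 ± 0.00884 (15 of 15 tumours each) and cycle genes by 0.0577 ± 0.0520 (8 of 11), and interferon genes were positive in 13 of 15. Spearman correlation gave 0.0348 for mesenchymal genes. Squamous genes could be scored in 4 tumours (0.142 ± 0.0407), too few for the exact test to reach 0.05.

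**Figure D2:**
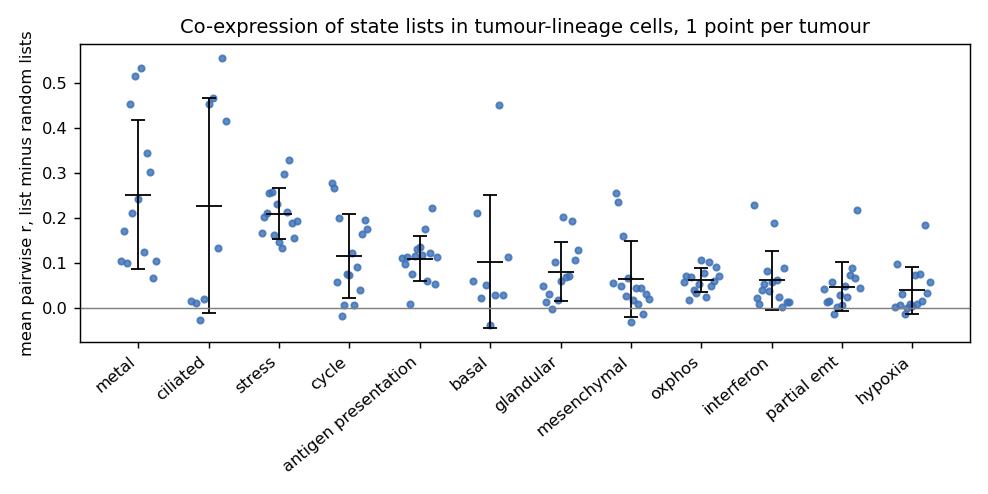
Mean pairwise correlation of each state list over tumour-lineage cells minus that of matched random lists, with 1 point per tumour and the mean ± SD. Stress genes lie above 0 in all 15 tumours, with a mean of 0.209.

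The same lists were compared between tumour-lineage cells and the other named cells of each tumour (log2 of the shares of UMIs, mean ± SD, n = 15; sign-flip permutation, two-sided). Classes were named by lineage markers, and malignant cells were not told from normal cells of the lineage. Higher epithelial genes and lower immune or stromal genes in the tumour-lineage class thus follow in part from the naming. Glandular genes, which encode secreted epithelial proteins, were higher in tumour-lineage cells by 4.65 ± 1.41 in 15 of 15 tumours (adjusted p = 4.0e-04), with SCGB1D2, SCGB2A1, MUC5B and LCN2 highest. Ciliated (2.46 ± 2.25), basal (1.74 ± 1.35) and oxidative phosphorylation genes (0.44 ± 0.30) were higher in 13 of 15 each. Antigen presentation genes were lower in 15 of 15 (-2.71 ± 1.22), with HLA-DPB1 at -5.10 ± 2.25. Mesenchymal genes were lower in 11 of 15 tumours (-2.26 ± 2.98, adjusted p = 0.0152), with the matrix genes COL3A1 at -4.04 and SPARC at -3.92, as were stress (-1.05 ± 0.76, 13 of 15), squamous (-2.19 ± 2.14, 12 of 15) and cycle genes (-0.69 ± 1.05, 11 of 15, adjusted p = 0.0356). The squamous list was led by S100A8 (-3.57) and S100A9 (-3.14), which neutrophils and monocytes also express, while KRT6A stood at 4.55 in the 4 tumours that had it. Hypoxia (0.30 ± 1.07), interferon (-0.36 ± 1.02), metallothionein (-0.33 ± 1.66) and partial EMT genes (-0.21 ± 1.37) did not pass. With the mean over genes of log2 ratios, cycle (adjusted p = 0.116) and squamous genes (-0.44, adjusted p = 0.507) no longer passed and interferon genes did (-1.10 ± 1.04, adjusted p = 7.9e-04). In the 11 carcinomas with epithelial-like cells, cycle genes no longer passed (permutation, adjusted p = 0.202) and mesenchymal genes stood at -3.40 ± 2.63.

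Dissociated cells and sections of the same 8 tumours were compared by the share of UMIs that each state list took. Such a share also moves with the mix of cells in each assay, which was examined for stress genes only. Stress genes took 1.83% of UMIs in cells and 0.291% in sections, higher in cells by 2.76 ± 1.03 on the log2 scale in 8 of 8 tumours (mean ± SD, n = 8; exact sign-flip permutation, two-sided, p = 0.00781, the smallest possible, adjusted p = 0.0254). FOSB (6.09 ± 2.70), HSPA1A (3.93), ATF3 (3.79) and KLF6 (3.65 ± 0.995) led. The stress share stood above the section's both in tumour-lineage cells (2.14 ± 1.45) and in all other cells (3.21 ± 0.92). Antigen presentation genes were higher in cells by 1.06 ± 0.76 in 7 of 8 tumours (exact permutation adjusted p = 0.0406), HLA-DRB1 most. Glandular (-1.46 ± 1.22), oxidative phosphorylation (-1.16 ± 0.40) and mesenchymal genes (-1.03 ± 0.75) were lower in cells in 8 of 8 tumours each, with COX6A1 at -3.27 ± 0.71, MMP2 at -2.58 and TAGLN at -2.24. Squamous (2.36 ± 2.65), hypoxia (0.33 ± 0.31), cycle (0.30 ± 0.49), partial EMT (0.23 ± 0.81), metallothionein (-0.12 ± 0.95), interferon (-0.22 ± 0.59), basal (-0.25 ± 0.56) and ciliated genes (-0.32 ± 1.27) did not pass. Tumours were paired by title; without that pairing 4 of 13 lists passed in place of 5, glandular genes no longer, and without subtracting the median of all genes 8 passed, with cycle, hypoxia and squamous genes added. With the mean over genes of log2 ratios, antigen presentation (exact permutation, adjusted p = 0.0677) and mesenchymal genes (0.0508) no longer passed.

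**Figure D3:**
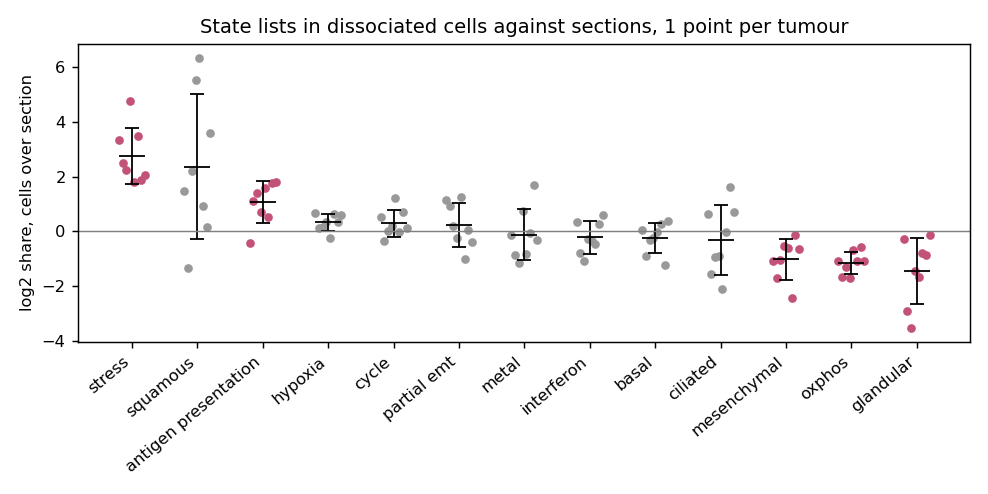
Log2 ratio of each state list's share of UMIs in dissociated cells over that in the section of the same tumour, with 1 point per tumour, the mean ± SD over 8 tumours and lists past the threshold in pink. Stress genes lie at a mean of 2.76.

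Across the spots of the 10 sections, each state score was correlated with the score of 7 microenvironment cell types, holding the spot's UMIs and its tumour lineage score fixed. Mesenchymal genes went with fibroblast markers (partial rho 0.561 ± 0.247, mean ± SD; positive in 10 of 10 sections; permutation p = 0.00195, the smallest possible, adjusted p = 0.0127), led by SPARC (0.433 ± 0.232), FN1 and COL6A1, which fibroblasts themselves express. Antigen presentation genes went with macrophage markers (0.450 ± 0.180), with CD74 at 0.404 ± 0.179, and with T or NK markers (0.261 ± 0.117), endothelial (0.156 ± 0.1003) and B markers (0.0995 ± 0.0809). Partial EMT genes went with fibroblast markers (0.193 ± 0.199), led by the secreted factors INHBA (0.206), PLAU (0.198) and TGFBI (0.189). Section OVCA1 reached 0.689 and the nearest other section 0.321. The values do not say which cells of a spot held these genes. Interferon genes went with macrophage (0.148 ± 0.0958), T or NK (0.108 ± 0.0732), fibroblast (0.0955 ± 0.0805), endothelial (0.0612 ± 0.0443) and B markers (0.0371 ± 0.0288), with ISG15 and LY6E highest. Stress genes went with fibroblast markers (0.163 ± 0.120, 9 of 10 sections, adjusted p = 0.0232), led by EGR1, DUSP1 and FOS, and with macrophage (0.109 ± 0.0910), mural (0.102 ± 0.0672), endothelial (0.0985 ± 0.0599) and T or NK markers (0.0789 ± 0.0590). Mesenchymal genes also went with mural (0.305 ± 0.179), endothelial (0.183 ± 0.0943), macrophage (0.137 ± 0.116) and T or NK markers (0.104 ± 0.0904).

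Glandular genes went against fibroblast markers (-0.201 ± 0.140), with AGR2 at -0.185 and WFDC2 at -0.172, and against mural (-0.107 ± 0.0851), T or NK (-0.0793 ± 0.0429), endothelial (-0.0792 ± 0.0596) and macrophage markers (-0.0699 ± 0.0358). Hypoxia genes went against plasma markers (-0.0862 ± 0.0975, adjusted p = 0.0342). In all, 26 of 91 pairs passed, 20 positive and 6 negative; no pair of the cycle, oxidative phosphorylation, metallothionein, squamous, basal or ciliated lists did. With the 7 BRCA, OVCA, UCEC and PDAC sections alone, without GIST and LIHC, 0 of 91 pairs passed the sign-flip test, 33 having an unadjusted p under 0.05, the smallest possible exact p being 0.0156. Of the 26 calls, 9 ended with the cell type score of neighbouring spots, 9 without the tumour lineage score as a covariate, 6 in spots at or above the median of that score, 3 with spots of at least 2000 UMIs and 2 with partial Pearson correlation.

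**Figure D4:**
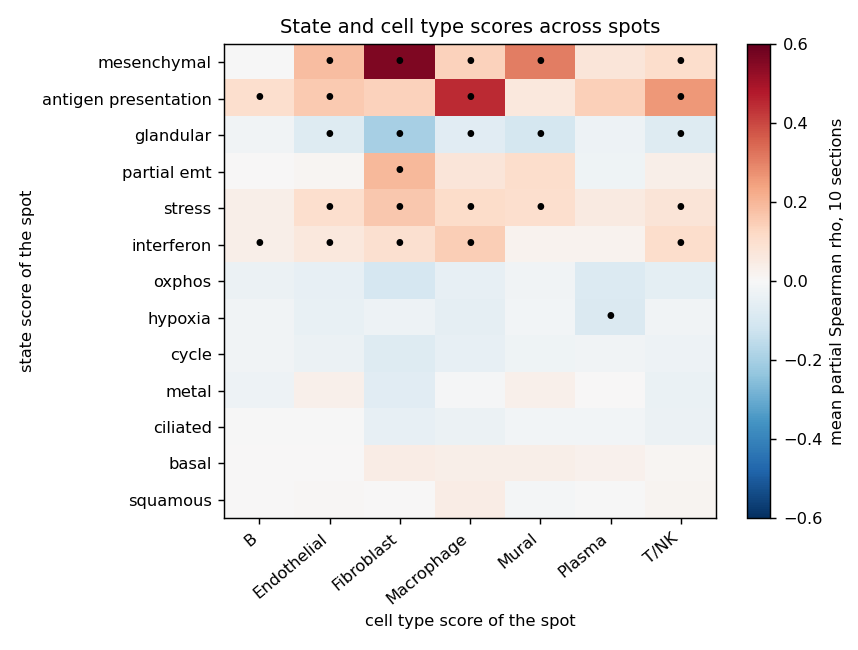
Mean partial correlation across spots, over 10 sections, of each state list (down) with each cell type list (across), with dots where the adjusted p was under 0.05. The highest value is mesenchymal with fibroblast at 0.561.

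In the melanoma xenograft the species of a transcript parts tumour from host. Human state scores and mouse cell type scores were correlated across the spots of both sections, with human and mouse UMIs held fixed, and no test was run on 2 sections. Of 96 pairs measured in both, 54 had the same sign and 0 reached 0.1 in size in the same direction in both. Each section was shallow in 1 species, with a median of 145 human UMIs per spot in the first and 259.5 mouse UMIs in the second. Scores of that species are therefore weak, and the lack of agreement does not show that no pair goes together. Human mesenchymal genes with mouse fibroblast markers stood at 0.157 and 0.037, hypoxia genes with monocyte markers at 0.009 and 0.134, and hypoxia genes with endothelial markers at 0.001 and -0.130. Without control for UMIs 20 pairs reached 0.1 in both, and 5 did with partial Pearson correlation.

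FC1242 tumour cells from a library named for Rag knockout were compared with those of a library named for wild type, which asks what tumour cells express without T and B cells. Rag1 and Rag2, which encode the recombinase of lymphocyte receptor genes, had 0 UMIs in both libraries, so they could not check the genotype at this depth (floors of 3 UMIs, 0.0714 and 0.0715 CPM). T-like cells were 9 of 8153 (0.110%, 95% exact Clopper-Pearson interval 0.0505 to 0.209%) in the knockout library and 51 of 6674 (0.764%, 0.569 to 1.00%) in the wild-type one. Each library had 4 tagged pools of epithelial-like cells, and the labels do not say whether a tag marks 1 mouse. Their cells spread unevenly over clusters that held cells of both libraries. Cluster 8 held 103 of 510 in the knockout and 126 of 2675 in the wild-type library. Cluster 0 held 30 and 490, and cluster 1 held 31 and 358. Other clusters were closer in share, such as cluster 6 (10.4% and 11.7%) and cluster 3 (8.82% and 9.72%). Genes of class I antigen presentation fell in the knockout pools (CPM as mean ± SD, n = 4 pools per group; log2 fold change ± SE). Psmb9, a subunit of the immunoproteasome, fell by 2.34 ± 0.21, from 97.5 ± 11.7 to 17.7 ± 9.23 CPM (adjusted p = 4.7e-05). The class I heavy chain gene H2-K1, which shares reads with H2-D1 and H2-Q4, fell by 1.81 ± 0.16, from 1311 ± 295 to 372 ± 78.3 CPM (adjusted p = 4.7e-05). Nlrc5, the activator of class I transcription, fell by 2.90 ± 0.43 (adjusted p = 0.00199) and the peptide transporter gene Tap1 fell by 1.68 ± 0.23 (adjusted p = 0.00114). Iigp1, an interferon-gamma induced GTPase, fell by 3.20 ± 0.35, from 44.1 ± 9.77 to 4.03 ± 2.97 CPM. H2-Q4 (-2.44 ± 0.41), the GTPase gene Ifi47 (-1.79 ± 0.28), Arc (-2.06 ± 0.44), Grik5 (-1.87 ± 0.42) and Taf10, a general transcription factor subunit (-1.72 ± 0.11, adjusted p = 1.8e-06), were the other named genes that fell.

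In the same pools a different set of interferon genes rose. Ifit3, an antiviral gene that shares reads with Ifit3b, rose by 2.22 ± 0.40 (136 ± 98.7 against 28.7 ± 15.6 CPM, adjusted p = 0.00551), Ifit1 by 1.60 ± 0.37 (147 ± 72.9 against 48.2 ± 26.9 CPM), Irf7, a factor of type I interferon induction, by 1.51 ± 0.30 and Oasl1 by 1.98 ± 0.32. In knockout pool F_1 Ifit3 stood at 266 CPM on unscaled totals, and at most at 96.5 in the other knockout pools. Irf7 stood at 103 CPM in the same pool and at most at 45.7 in the others. Over all epithelial-like cells, with or without a tag, the ratio of the libraries was -0.05 for Ifit1, -0.09 for Irf7, -0.22 for Isg15 and -0.54 for Bst2, opposite to their rise in the tagged pools, 0.52 for Ifit3 and 0.03 for Ly6e. By the same measure H2-K1 was at -3.11, Psmb9 at -3.92 and Tap1 at -3.12. Tagged cells were 613 of 7434 in the knockout library and 3060 of 5915 in the wild-type one, and H2-K1 was higher in tagged than in untagged cells by 2.48 and 3.00 on the log2 scale. Across these cells H2-K1 rose with the count of the top tag (Spearman rho 0.301 in the knockout and 0.745 in the wild-type library; cells are not independent replicates). The fatty acid receptor gene Ffar4 rose by 3.02 ± 0.59, and by 1.37 without knockout pool F_1, which held 178 CPM on unscaled totals against at most 24.8 in the other 3 knockout pools. Tm4sf4 rose by 2.34 ± 0.40, and by 1.45 without the same pool. The other named genes that rose were S100a14 (2.31 ± 0.38), Ifit3b (1.96 ± 0.39), Slfn2 (1.78 ± 0.28) and Vnn1 (1.74 ± 0.31).

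**Figure D5:**
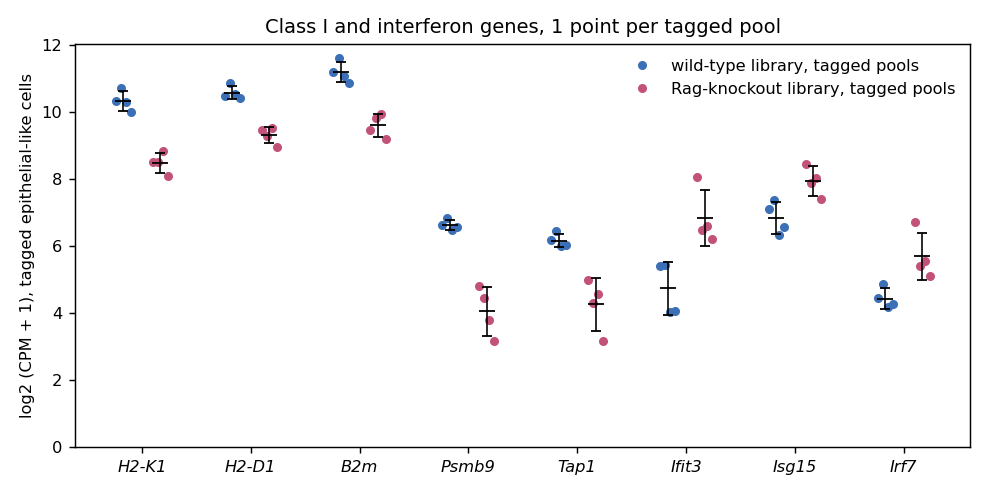
Log2 of CPM plus 1 (on unscaled totals) of class I and interferon genes in the 4 tagged pools of the knockout library and the 4 of the wild-type library, with points for pools and black bars for the mean ± SD of the log values. Psmb9 lay between 7.89 and 27.2 CPM in the knockout pools and between 87.6 and 113 in the wild-type pools.

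By list, 6 of 8 antigen presentation genes fell (7 when adjusted over the list alone), including B2m (-1.54 ± 0.17), and Psmb8 missed the threshold (-1.25 ± 0.45, adjusted p = 0.0891). In the interferon list 6 of 13 rose (9 over the list alone); Cxcl10 (1.23 ± 0.55) did not pass. Cycle genes rose in 7 of 16 (8 over the list alone), such as Rrm2 (1.07 ± 0.19) and Cdk1 (0.76 ± 0.15), hypoxia genes in 6 of 14 (8 over the list alone), such as Adm (1.05 ± 0.19) and Ldha (0.47 ± 0.07), and oxidative phosphorylation genes in 6 of 13 (9 over the list alone). Partial EMT genes rose in 5 and fell in 1 of 10 (6 and 2 over the list alone). Mesenchymal genes fell in 4 of 9, among them Igfbp7 (-1.23 ± 0.23) and Col6a2 (-0.63 ± 0.11), and Vim rose, with the same counts over the list alone. Glandular genes rose in 3 of 6 (4 over the list alone), such as Muc1 (2.15 ± 0.52) and Wfdc2 (1.10 ± 0.23), squamous genes in 2 of 4, such as Sprr1a (1.97 ± 0.40), and 1 of 2 metallothionein genes, with 2 and 1 over the list alone. Basal genes had 1 rise and 1 fall of 3, and stress genes 1 rise and 1 fall of 15 (1 and 2 over the list alone). Epithelial markers rose in 4 of 7 (6 over the list alone), Epcam by 1.85 ± 0.48. Among markers of other cells, Mrc1 rose (1.30 ± 0.23; 1 of 2 macrophage markers), 2 of 2 mesothelial markers rose, 1 of 2 monocyte and 1 of 3 hepatocyte markers fell, and 0 of 4 fibroblast and 0 of 1 acinar markers passed. Over the list alone, 2 macrophage markers were higher and monocyte markers had 1 higher and 1 lower. No ciliated gene and no neutrophil, dendritic, T, NK, B, endothelial, mural or erythroid marker had enough counts in these sums to be tested.

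In all, 478 genes rose and 493 fell of 9090 (edgeR, two-sided), and groups did not overlap for 810 of the 971, against 16.4% of all genes and 2.86% by chance. Since each genotype had 1 library, the p-values cover the spread between tagged pools only. The count was 614, 445 and 552 without knockout pool F_2 and wild-type pools F_1 and F_2, 1624 with all cells of each tag and 555 with the wild-type pools thinned to the knockout depth.

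Tumour cells from a library named for liver were compared with those of a library named for peritoneum, which asks whether the site of growth changes the same line (2 tagged pools each; CPM as mean ± SD, n = 2; log2 fold change ± SE). Per the labels, the liver tumours came from 1000000 cells injected in the spleen and the peritoneal ones from 100000 injected in the peritoneum, so site, route and dose cannot be told apart. The tagged epithelial-like cells spread unevenly over clusters that held cells of both sites. Cluster 0 held 342 of 582 in liver and 427 of 1799 in peritoneum, cluster 1 held 13 and 573, and cluster 5 held 3 and 158. Cluster 2 held a like share of each, 17.9%. Antigen presentation genes rose in liver in 11 of 13 (11 when adjusted over the list alone): Ciita, the class II activator, by 2.69 ± 0.37, Psmb9 by 1.97 ± 0.18, Tap1 by 1.88 ± 0.16 and H2-K1 by 0.61 ± 0.16. Interferon genes rose in 7 and fell in 1 of 16 (the same counts over the list alone), with the chemokine Cxcl10 at 1.77 ± 0.47 and Ifit3 at -1.21 ± 0.33. Cycle genes rose in 14 of 16 (16 over the list alone), such as Mki67 (1.47 ± 0.09) and Hmgb2 (1.42 ± 0.08). The class II genes of the list stood at 0.323% (H2-Aa) to 0.582% (H2-DMa) of their level in the monocyte-like cells of the library, against 64.4% for Psmb9 and 57.7% for Tap1. H2-K1 was higher in tagged than in untagged cells here too, by 1.13 in liver and 1.41 in peritoneum (Spearman rho with the top tag count 0.255 and 0.604). Over all epithelial-like cells, with or without a tag, the log2 ratio of liver to peritoneum was 0.88 for H2-K1, 2.32 for Psmb9 and 2.24 for Tap1, and the 2 genes short of the test moved from 0.19 to 0.45 (H2-D1) and from -0.09 to 0.56 (Psmb8).

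Matrix, hypoxia and stress genes fell in liver. Mesenchymal genes fell in 10 of 11 (10 over the list alone), with the matrix glycoprotein Sparc at -2.43 ± 0.14, Col1a1 at -3.42 ± 0.45 and Fn1 at -1.06 ± 0.15. Col1a1 in peritoneal tumour cells stood at 0.126% of its level in that library's fibroblast-like cells, against 11.7% for Sparc and 20.3% for Fn1, and fibroblast-like cells were 158 of 5248 in the peritoneum library and 26 of 3521 in the liver library. Hypoxia genes fell in 11 of 14 (13 over the list alone), with the peptide hormone gene Adm at -2.72 ± 0.49 and Ankrd37 at -1.68 ± 0.15. Stress genes fell in 12 of 15 with Hspa1b risen (12 and 1 over the list alone), such as Ier3 (-1.70 ± 0.21) and Atf3 (-1.64 ± 0.12). Partial EMT genes fell in 8 of 10 and Itga2 rose (8 and 1 over the list alone), with Inhba, an activin subunit, at -2.92 ± 0.30 and the laminin gene Lamb3 at -2.54 ± 0.41. Squamous genes fell in 3 and rose in 1 of 6, with the keratin gene Krt6a at -2.66 ± 0.20, basal genes rose in 1 and fell in 1 of 3, glandular genes fell in 1 of 8, oxidative phosphorylation genes rose in 4 of 13 and metallothionein genes in 1 of 2, each with the same counts over the list alone; 0 of 2 ciliated genes passed.

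The named genes that rose included Neurl1b, a ubiquitin ligase of the Notch pathway (2.97 ± 0.20; 26.9 ± 2.92 against 3.46 ± 0.844 CPM), Mpeg1 (3.60 ± 0.48), Apol6 (3.32 ± 0.50), Tnfsf10 (3.17 ± 0.58), Padi4 (3.13 ± 0.78), Myb (3.06 ± 0.43), Rprml (3.01 ± 0.56), Wnt6 (2.99 ± 0.66) and Ankef1 (18 UMIs against 0). Mpeg1, a macrophage gene, stood at 2.40% of its level in the highest other class, and Tnfsf10, Padi4 and Myb at 2.23%, 2.23% and 2.87%. Among genes that fell, Sulf1 stood at 0.504% of its level in fibroblast-like cells of the peritoneum library, Prss23 at 1.84% of that in endothelial-like and Chst11 at 2.53% of that in neutrophil-like cells. Wisp2 (-6.25 ± 0.36; 0.272 ± 0.117 against 19.7 ± 3.88 CPM) and Nrep (-4.60 ± 0.46) fell, as did Try5, Fbxo32 and Prss23, each with 2 UMIs in liver against 237, 138 and 131. Chst11, Trdc, Pcdhb16, Ctcflos and Sulf1 had 0 UMIs in liver against 72, 65, 50, 39 and 31.

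Markers of other cells moved as well. Fibroblast markers fell in 5 of 6 (Dcn at -3.97 ± 0.82) and C3 rose, endothelial markers fell in 2 of 4 (2 higher and 2 lower over the list alone), and macrophage markers had Mrc1 risen (2.16 ± 0.12) and Apoe fallen (-1.31 ± 0.13) of 8. The B marker Ighm rose by 5.15 ± 0.85 and the T marker Trac fell by 1.45 ± 0.26, each the only member measured, and Trf rose, 1 of 4 hepatocyte markers. Monocyte markers had 1 rise and 1 fall of 3, the fall being Fn1, also counted among the mesenchymal genes. Dendritic markers had 1 rise of 2 (1 higher and 1 lower over the list alone), neutrophil markers 1 fall of 2 and mesothelial markers 1 fall of 2. Epithelial markers had 4 falls of 7, Epcam at -2.97 ± 0.70 (1 higher and 4 lower over the list alone). Of the mural and acinar markers, 0 of 3 (2 lower over the list alone) and 0 of 2 passed. In all, 1907 genes rose and 2067 fell of 11858 (edgeR, two-sided), all with groups that did not overlap, against 70.9% of all genes and 33.3% by chance. Each site had 1 library, so the p-values cover the spread between tagged pools only; the count was 2394, 2579 and 2505 without liver pool 1, liver pool 2 and peritoneum pool 1.

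The library of pancreas and peritoneum tumours held 2 tagged pools of each site, and their comparison was added after the data were seen. In peritoneum Cxcl2, a neutrophil chemokine, rose by 1.74 ± 0.14 (45.6 ± 3.87 against 13.6 ± 0.532 CPM, mean ± SD, n = 2 pools) and the collagen gene Col3a1 by 1.35 ± 0.12. Gpx2, a glutathione peroxidase (-2.35 ± 0.20), the apolipoprotein gene Apoa1 (-1.86 ± 0.18), the lectin gene Lgals4 (-1.25 ± 0.12) and Atp1b1 (-1.23 ± 0.12) were among the genes that fell (edgeR adjusted p = 0.0433 for each). Of the mesenchymal list, 1 gene rose and 1 fell of 11 (3 and 2 when adjusted over the list alone). Over the list alone, 12 of 16 interferon, 10 of 15 stress, 7 of 15 hypoxia, 2 of 2 metallothionein, 2 of 9 squamous and 1 of 10 glandular genes and 7 of 8 epithelial markers were lower and 0 higher, with 0 past the test over all genes. All 12 antigen presentation genes were negative, 0 past either adjustment. In this library H2-K1 stood at 654 CPM in tagged and 71.7 CPM in untagged cells (unscaled totals; Spearman rho with the top tag count 0.711), and cells without a tag have no site. Cluster 0 held 427 of the pancreas and 112 of the peritoneum cells (20.3% and 5.40%). Further, 0 cycle, oxidative phosphorylation and ciliated genes passed; partial EMT had 2 higher and 3 lower of 12 and basal 1 higher of 3 over the list alone. Among markers of other cells, 1 of 7 fibroblast markers rose (3 over the list alone), 1 of 4 hepatocyte markers fell (2 over the list alone), 1 monocyte and 1 mesothelial marker were lower over the list alone, and 0 macrophage, neutrophil, dendritic, T, B, endothelial, mural, acinar and erythroid markers passed. No NK marker was measured in the tumour cell sums of any mouse comparison.

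In all, 5 genes rose and 5 fell of 12598, with groups that did not overlap for 42.6% of all genes, against 33.3% by chance; mt-Nd3, 2510017J16Rik and Gm8251, left out by the naming rule and named after their values were seen, were the others that rose. The count was 419, 299, 101 and 273 without pancreas pools 1 and 2 and peritoneum pools 1 and 2, 259 with DESeq2, 902 without the filter on low counts and 0 with all cells of each tag, where edgeR had 1581 genes at an unadjusted p under 0.05. With the tag number as a block it was 1069.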

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

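The splits of the tumours and pools, the tests of the choice of cells by their tag and the question of the 2 libraries were chosen after the results were seen, as was the setting with thinned pools, whose bound was written before its value; the test of macrophage RNA was not. Each group of 4 to 10 samples behind a named result was searched for a sample far from the others, which chance gives in about 1 in 20 groups; 4 of 82 groups had one, where chance gives about 4.1. Of 39 pairs of groups 0 differed in the direction of the same contrast.

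Across spots, the interferon list with B markers reached a partial rho of 0.108 in section LIHC1, the nearest of the other 9 being 0.0475. The partial EMT list with fibroblast markers reached 0.689 in section OVCA1, the nearest being 0.321. In the Rag knockout pools, Ffar4 stood at 178 CPM (unscaled totals) in pool F_1, the nearest of the other 3 pools being 24.8. Ifit3 stood at 266 CPM in pool F_1, the nearest being 96.5. Pool F_1 also stood apart over all genes, so these flags may not be separate events. Its chi-square per degree of freedom was 3.69, 4.10 and 3.85 against F_2, M_1 and M_2, and 1.53 to 1.63 among those pools.

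Class I genes fell and several interferon genes rose in the tagged pools of the knockout library. Of the 35 splits of the 8 pools into 4 and 4, only the real one, 1 split, gave as many genes (971, the highest other 1). This argues against chance between pools but does not exclude it, since 1 in 35 is the smallest share possible. Every other split mixes pools of the 2 libraries, so a difference between libraries enters its spread. For the lower class I genes, the values argue against the choice of tagged cells as the whole cause. The median log2 ratio of the 6 fallen members over all epithelial-like cells was -2.66. In cells without a single tag they were also lower, from -2.63 (Psmb9) to -0.59 (Tap2), with H2-K1 at -1.58. On only 2 measured markers, less macrophage RNA is argued against too (these stood at 0.95). With the wild-type pools thinned the median was -1.62. Thinning leaves a gene's expected share of UMIs unchanged, so this value cannot tell whether fewer UMIs were a cause. For the higher interferon genes, the choice of tagged cells may be part of the source and stays open: the median of the 6 risen members over all epithelial-like cells was -0.0694, and in cells without a single tag Ifit3 (0.95), Ly6e (0.65) and Ifit1 (0.43) were still higher while Irf7 (-0.0140), Isg15 (-0.0615) and Bst2 (-0.23) were not. With 1 library per genotype, a difference between the 2 libraries other than the genotype cannot be told apart from it. The genotype stays open and untested, and Ifng had 0 UMIs in the 9 T-like cells of the knockout library and 8 in the 51 of the wild-type library, too few to test.

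The counts for human tumours had 10 splits of 6 tumours each, too few for a share under 0.05. OVCA against BRCA gave 64 genes and the highest other split 0, UCEC against BRCA gave 55 and 0, and OVCA against UCEC gave 0 and 0, so that 1, 1 and 10 of 10 splits gave as many genes as the real one.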

How the results depend on the processing

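Fits with only the 2 groups compared, the thinned pools, the tag as a block, the cells without a tag and every alternative of peritoneum against pancreas were chosen after the results were seen. With DESeq2 the genes called were 736 in place of 64 (OVCA against BRCA), 850 in place of 55 (UCEC against BRCA), 3 in place of 0 (OVCA against UCEC) and 259 in place of 10 (peritoneum against pancreas). Without the filter on low counts they were 152, 135 and, for peritoneum against pancreas, 902. With all cells of a tumour or tag they were 11 (OVCA against BRCA), 100 (UCEC against BRCA), 1624 in place of 971 (Rag knockout) and 0 (peritoneum against pancreas, where edgeR had 1581 at an unadjusted p under 0.05); liver against peritoneum gave 3730, of which 1914 were shared with the 3974. With cells of at least 1000 UMIs, UCEC against BRCA gave 83; with only the 2 groups compared in the fit, OVCA against BRCA gave 10 and UCEC against BRCA 238. Thinned wild-type pools, with fewer UMIs by construction, gave 555 for Rag knockout. The causes of these changes were not tested.

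Leaving out 1 tumour at a time gave 6 to 203 genes for OVCA against BRCA: 8, 18 and 147 without BRCA replicates 1, 2 and 3, and 203, 28 and 6 without OVCA replicates 1, 2 and 3, with 6 to 54 shared with the full set. UCEC against BRCA gave 4 to 138: 7 and 138 without BRCA replicates 1 and 3, and 6, 14 and 4 without UCEC replicates 1, 2 and 3, with 4 to 51 shared. OVCA against UCEC gave 0 each time. Leaving out 1 pool at a time gave 445 to 990 for Rag knockout (614 without knockout F_2, 445 and 552 without wild-type F_1 and F_2; 441 to 799 shared), 2394 to 2858 for liver against peritoneum in place of 3974 (2394 and 2579 without liver pools 1 and 2, 2505 without peritoneum pool 1; 2306 to 2674 shared) and 101 to 419 for peritoneum against pancreas (419 and 299 without pancreas pools 1 and 2, 101 and 273 without peritoneum pools 1 and 2; 10 shared each time); the lone pool left is assumed to vary like the others.

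With the replicate number as a block, OVCA against BRCA gave 61 genes (41 shared) and UCEC against BRCA 45 (28 shared); with the tag as a block, Rag knockout gave 704, liver against peritoneum 4493 and peritoneum against pancreas 1069. The numbers name patients or tags: correlations of samples with the same number, after removing group means, were -0.08 to 0.19 in human tumours, -0.04 to 0.07 in knockout and wild-type pools, 0.25 in liver and peritoneum and 0.50 in pancreas and peritoneum. Over every epithelial-like cell, with or without a tag, Bst2 (-0.54), Ifit1 (-0.0512), Irf7 (-0.0877) and Isg15 (-0.22) lay opposite to their rise in the tagged pools; the test of tagged cells in the part above bears on this. Lists that differ between cells and sections numbered 3 with the mean over genes and 8 without subtracting the median, in place of 5. Pairs across spots numbered 0 in place of 26 with the 7 BRCA, OVCA, UCEC and PDAC sections alone (33 at an unadjusted p under 0.05), where the smallest possible exact p of 0.0156 sets the limit. They numbered 19 with the cell type score of neighbouring spots and without the tumour lineage score as a covariate (9 of the 26 ended in each), 22 in spots at or above the median of that score (6 ended), 25 with spots of at least 2000 UMIs (3 ended) and 29 with partial Pearson (2 ended). Xenograft pairs numbered 20 without control for UMIs and 5 with partial Pearson, in place of 0. Co-expressed lists numbered 10 to 12. The ciliated and basal lists fell short with cells thinned to 500 UMIs (exact permutation, adjusted p = 0.0682 and 0.219). Each was then scored in 6 tumours, with a mean excess of 0.220 and 0.0702. Lists that differ between tumour and other cells numbered 8 to 9 under their alternatives. With the mean over genes, cycle and squamous genes dropped out and interferon genes came in. Cycle genes also dropped out in the carcinomas with epithelial-like cells. Of the values of the called genes named in the comparisons under the alternatives, 169 of 273 stayed past the threshold in OVCA against BRCA, 179 of 260 in UCEC against BRCA, 321 of 327 in Rag knockout, 223 of 234 in liver against peritoneum and 70 of 77 in peritoneum against pancreas; apart from the 4 genes given above, the others kept their direction. The human tests called few genes short of large changes: 5.15% of genes simulated at 4-fold were called in OVCA against BRCA, and 99% at 64-fold. Knockout pools, whose sums are of a like depth, recovered 81.6% of genes at 2-fold, so depth alone is not shown to be the cause.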

Other observations

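The classes of cells differed between the libraries named for liver and peritoneum. Percentages are of all cells of a library, tumour cells included, so they are not shares of the host cells. Epithelial-like cells were 753 of 3521 in liver (21.4%, 95% exact Clopper-Pearson interval 20.04 to 22.8%) and 3571 of 5248 in peritoneum (68.0%, 66.8 to 69.3%). Monocyte-like cells were 24.7% (23.3 to 26.1%) against 0.781% (0.561 to 1.06%), T-like cells 7.55% (6.70 to 8.48%) against 0.743% (0.529 to 1.01%), NK-like cells 4.60% (3.93 to 5.35%) against 0.210% (0.105 to 0.375%) and B-like cells 215 against 1. Macrophage-like cells were 13.5% (12.4 to 14.7%) against 15.9% (14.9 to 16.9%). By count, they were the largest named host class in peritoneum, with 835 cells against 158 fibroblast-like ones. In liver the 475 macrophage-like cells came after 869 monocyte-like ones. Ifng, the gene of interferon-gamma, had 111 UMIs in 46 NK-like cells and 170 in 67 T-like cells of the liver library and 46 in 8 T-like cells of the peritoneum library. In the pancreas and peritoneum library 7637 of 8773 cells were epithelial-like (87.1%, 86.3 to 87.7%), 315 macrophage-like and 140 T-like, with 20 Ifng UMIs in 13 of the T-like cells.

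Of the 2604 xenograft cells, 2464 were human (94.6%, 93.7 to 95.5%), 29 mouse (1.11%, 0.747 to 1.60%) and 111 mixed. The human cells held the pigment cell genes PMEL (1787 CPM), S100B (1374 CPM), MLANA (1242 CPM), DCT (705 CPM), MITF (455 CPM) and SOX10 (105 CPM). The mouse cells held the macrophage genes Apoe (13554 CPM), C1qa (6215 CPM) and Cd68 (1723 CPM). In the human cells the co-expression excess was highest for hypoxia (0.279), stress (0.257) and cycle genes (0.255), followed by mesenchymal (0.0969), partial EMT (0.0815) and oxidative phosphorylation genes (0.0720), each with a mean r above the highest random list. Metallothionein genes stood at 0.106, their mean r of 0.150 lying under the highest random list at 0.186. The excess stood at 0.0157 for antigen presentation, 0.0106 for ciliated and -0.0132 for interferon genes, with no replicate.

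The test of free fibroblast RNA was chosen after the results were seen; those of the mix of cell types and of RNA from other cells were not. Stress genes stood higher in dissociated cells than in sections of the same tumours. The lower of the shares in tumour cells and in other cells still exceeded the section's by 2.09 ± 1.41 (mean log2 ± SD), in 8 of 8 tumours, least in LIHC1 (0.235). This argues against a different mix of tumour cells and other cells as the whole cause. The other cells were taken as 1 group, so a shift among their types between the assays was not tested. The dissociation of the tissue, the chemistry of the 2 assays and such a shift may each account for the rise, and the design does not part them.

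Mesenchymal genes fell in liver against peritoneum. RNA from other cells as the whole cause of the 640 genes that fell by over 1 (log2) cannot be told from the tables: 30.8% of them (interval 27.2 to 34.5%) stood higher in peritoneal tumour cells than in every other class, 0 of them mesenchymal genes, and the interval holds the bound set in advance. Free RNA of fibroblast-like cells as the whole source of the 10 fallen mesenchymal genes is argued against, since their median was 12.3% of the fibroblast-like level, against a median of 0.238% for the 6 fibroblast markers outside the list (Col6a3 at 25.9%, the other 5 at 0.0784 to 0.856%). It is not excluded for Col1a1 (0.126%) and Col1a2 (0.0532%), which lay at the level of those markers. The site of growth, the route and the dose (1000000 cells in the spleen against 100000 in the peritoneum) stay open as untested explanations, with 1 library per site.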
